A study of Mus musculus with 24 samples.

How the data were processed

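The signals analysed were deposited per-probe intensity values of 24 arrays, linear and not normalized per the file headers, each with a detection p-value per probe. Per the file headers the signals of the strains came in separate files, and the deposited series values were given as log2 values, quantile-normalized within each strain. Per the labels the RNA was purified with TRIsure and NucleoSpin RNA II columns and checked on a Bioanalyser, and cRNA was labelled with biotin using an Ambion MessageAmp kit. The scanner software, the authors' normalization settings, the slides on which arrays lay and the time of tissue collection were not given in the sources used here. Each column was matched to its sample by its label, and 0 columns were left without a sample.

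In the Balb/C file some detection p-values had lost their decimal point, and 313 cells on 11 arrays that read far above 1 were taken as 1. These cells belonged to the dimmest probes, in the lowest 0.258% of signals on their arrays. No other value was changed.

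Work was done in R 4.3.3 with limma 3.58.1 and the package data.table in version 1.17.8. Within each strain the signals were background-corrected by the normal-exponential model of the neqc function with the detection p-values, an offset of 16, quantile normalization and log2. A probe was kept when its detection p was below 0.05 on at least 3 of the 12 arrays of its strain, which left 20319 probes in C57Bl/6J and 19783 in Balb/C of 45281. Annotation gave 1 gene symbol to 34885 probes, several symbols to 18 and no listed gene to 10378, and 34807 were matched by Entrez identifier to the gene table of assembly GRCm38.p6. Each gene was measured by its brightest kept probe, for 10816 and 10669 genes. Group median signals and detected probes are described with the data, the arrays ranged from 124.2 to 139.8 in median signal with 17934 to 19262 detected probes in C57Bl/6J and from 95.3 to 110.2 with 17222 to 18592 in Balb/C, and replicates correlated between 0.985 and 0.993.

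A linear model with 4 group means was fitted per strain with limma, with 8 residual degrees of freedom and empirical Bayes variances whose prior degrees of freedom were 4.46 in C57Bl/6J and 8.03 in Balb/C. Contrasts were AngII against sham in each genotype, deficient against wild type in sham and under AngII, and the difference of the AngII responses. P-values were adjusted by Benjamini and Hochberg over all genes of a contrast, and genes below 0.05 were called. The difference of responses between strains was tested in a joint fit of 24 arrays over 9921 genes. A gene counted as separated when the ranges of both groups did not overlap.

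For the smallest folds a group was dim when its probe was detected on none of its 3 arrays. Each array of the dim group was then set to the higher of its value and the lowest normalized signal called detected on that array, and the fold was taken from the mean of these values to the mean of the brighter group.

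The genes named were fixed by a rule before testing. They were the 10 highest and 10 lowest log2 differences among called genes whose groups did not overlap, or the 5 smallest p-values where 0 genes passed, up to 4 called members of each list or its 2 brightest members, and always Nppa, Nppb, Acta1, Myh7, Myh6, Col1a1, Col3a1, Postn, Ccn2 and Timp1. Predicted genes and clone names were left out by this rule, and Gm9780 is named only for its position beside other called genes. Postn was not tested in C57Bl/6J, where its probes did not pass the filter. The 26 gene lists were written from general knowledge before the values were seen and were tested with camera at a preset correlation of 0.01, with camera at the estimated correlation and with fry, adjusted over the lists of a contrast. Agreement between contrasts was measured by correlation and by Fisher tests of shared calls.

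Alternative settings were no background correction, an offset of 50, scaling to a common median in place of quantiles, no filter, a stricter filter of detection p below 0.01, all detected probes, a trended prior, array weights, replicate number as a block, only the groups compared, the deposited series values and each array left out in turn. Further alternatives were added after the values were seen: the mean of a gene's detected probes, list medians under the normalizations, and each array left out between strains. Other splits of the same arrays were tested by counting called genes when 6 arrays were divided 3 against 3 (10 splits) and when both genotypes or strains were divided (100 splits).

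The steps were tested on simulated data with the noise of these arrays, in which 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. In C57Bl/6J the share of changed genes called was 34.3%, 91.0% and 98.5% for AngII against sham in wild type, 34.3%, 85.1% and 98.5% for the genotypes under AngII, and 10.4%, 64.2% and 95.5% for the difference of responses, with 6, 5 and 6 unchanged genes called. In Balb/C the shares were 20.9%, 74.6% and 100% for the first, 19.4%, 79.1% and 100% for the second, and 2.99%, 47.8% and 92.4% for the third, with 4, 5 and 3 unchanged genes called. Every changed gene that was called had the right sign, and 0 genes were called in contrasts without a simulated change. A matrix list shifted by 0.5 was found in both strains with 0 other lists called, but lists of correlated genes were not tested.

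Probes with several symbols or without a listed gene were left out of the gene tests, and sequences and positions of the Bmx probes were not analysed here.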

Results

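The data came from mouse left ventricle hybridized to Illumina expression arrays, 1 array per sample. Male mice of the strains C57Bl/6J and Balb/C, wild type or, as named here, deficient in the tyrosine kinase gene Bmx, had received AngII (angiotensin II) or a saline sham treatment for 2 weeks, and 24 arrays filled 8 groups of 3. The deficient groups were named KO in C57Bl/6J and TK in Balb/C. What these names stand for was not given, so "deficient" is a label, and loss of Bmx was not shown. The median signal of the groups lay between 127.53 (wild type sham) and 136.1 (wild type AngII) in C57Bl/6J and between 99.833 (wild type sham) and 107.17 (wild type AngII) in Balb/C. Between 18194 and 18758 probes were detected in the C57Bl/6J groups, and between 17338 and 18378 in the Balb/C groups. After filtering, 10816 genes were tested in C57Bl/6J and 10669 in Balb/C, each by 1 probe. The first principal component, with 33.2% of the variance in C57Bl/6J and 53.0% in Balb/C, separated the AngII arrays from the sham arrays in both strains.

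Gene values below are log2 differences with their standard errors from limma (n = 3 arrays per group). Adjusted p-values are Benjamini-Hochberg values over all genes of the comparison unless the list alone is named. "Rose" and "fell" are used for genes with an adjusted p below 0.05. When a probe was detected on none of the 3 arrays of the lower group, a smallest fold is given: the dim group was set no lower than the dimmest detected signal on its arrays. In differences of responses, a gene with such a group is given with its adjusted p and no size. The labels did not say that replicates came from separate animals, so the p-values measure the spread between these samples. With 3 arrays per group, the number of arrays limits precision. Of 26 gene lists, each was tested against all other genes with camera, first at the preset correlation between genes of 0.01 and then with the correlation estimated from the data. The list calls that also held with an estimated correlation were the hypertrophy genes and the IL-6 and STAT3 genes in the AngII response of C57Bl/6J wild type, and all other list calls were lost under it. A second list test, fry, asks on balance whether a list moved one way and, in its mixed form, whether its genes moved in either direction, and neither form compares the list with other genes.

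Bmx itself could not serve as a check of the genotype labels. Of its 4 probes, 1 was detected on all 24 arrays, with means of 6.42 ± 0.10 in sham and 6.53 ± 0.23 in AngII for C57Bl/6J wild type. It read 6.10 ± 0.11 and 6.25 ± 0.33 for the deficient mice (mean ± SD, n = 3). In Balb/C the same probe read 5.67 ± 0.10 and 5.50 ± 0.19 in wild type, and 5.71 ± 0.10 and 5.88 ± 0.14 in the deficient mice. The genotype difference of this probe was -0.32 in sham (adjusted p = 0.861) and -0.28 under AngII (adjusted p = 0.791) in C57Bl/6J, and 0.04 (adjusted p = 0.969) and 0.38 (adjusted p = 0.109) in Balb/C, with limma over all detected probes. The other 3 probes were near background, and 1 of them was detected on 1 of 3 arrays in each C57Bl/6J wild type group and on none in the deficient groups. Which part of the gene was changed was not given, and a probe outside it checks nothing.

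The first question was how the left ventricle of C57Bl/6J wild type mice differed after AngII from sham, 3 arrays against 3. Fetal and stress genes of the myocyte rose: skeletal actin Acta1 by 2.54 ± 0.32, the natriuretic peptides Nppb by 1.28 ± 0.12 and Nppa by 0.91 ± 0.19, and the calcineurin target Rcan1 by 1.67 ± 0.17. Myh7, the fetal myosin heavy chain, stood at 1.33 ± 0.48 (adjusted p = 0.11, 0.044 with a trended prior), and the adult form Myh6 at -0.13 ± 0.10 (adjusted p = 0.445). Genes for building and crosslinking the matrix rose as well, with Timp1, an inhibitor of matrix proteases, at 2.35 ± 0.31 and the collagen crosslinking enzyme Lox at 2.20 ± 0.38. So did the microfibril gene Mfap5 at 2.07 ± 0.30, Col8a1 at 1.88 ± 0.24 and Col3a1 at 1.49 ± 0.31. Col1a1 rose by 1.02 ± 0.28, and its call was lost when only the 6 arrays were fitted (adjusted p = 0.0819), without a filter on dim probes (adjusted p = 0.0622) and without each of 5 of the 6 arrays. The acute-phase gene Serpina3n rose by 2.30 ± 0.17, and the platelet and endothelial protein gene Mmrn1 rose at least 3.08-fold. Among the genes that fell most were the clock output gene Dbp at -2.23 ± 0.46, the cytokine-like gene Retnla at -2.12 ± 0.36, the mitochondrial carrier Ucp3 at -1.94 ± 0.37, and Wdfy1 at -1.82 ± 0.11. Further genes that fell were the muscle gene Ky at -1.80 ± 0.14, Lgals4 at -1.65 ± 0.14 and Hadha, an enzyme of fatty acid oxidation, at -1.57 ± 0.22.

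By list, 10 of 15 hypertrophy genes rose and 0 fell, with a median of 0.91, and this list kept its call (adjusted p = 0.0234 with an estimated correlation). Enah, an actin regulator, stood at 1.69 ± 0.31 and Xirp2 at 1.65 ± 0.19. Of 47 matrix genes 25 rose, 30 when adjusted over the list alone, and the median was 0.80 (adjusted p = 0.156 with an estimated correlation). IL-6 and STAT3 genes had a median of 0.41 and kept their call (adjusted p = 0.038 with an estimated correlation), with 5 of 22 higher, among them the iron-binding Lcn2 at 1.54 ± 0.22. Macrophage markers had a median of 0.39 with 9 of 33 higher, such as Ms4a6d at 1.15 ± 0.20 and the chemokine Ccl8 at 1.20 ± 0.24, and 1 lower (adjusted p = 0.122 with an estimated correlation). Fibroblast markers followed with 7 of 22 higher and a median of 0.25, led by Pi16 at 1.32 ± 0.16. Red cell genes had a median of 0.49, Slc4a1, the anion exchanger of erythrocytes, at 3.12 ± 0.39 and Alas2 at 1.72 ± 0.43. Both lists had an adjusted p of 0.191 with an estimated correlation. Epicardial genes had a median of 0.35, with Cldn15 the only 1 of 5 to pass (adjusted p = 0.278 with an estimated correlation).

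Lower lists in the same comparison were fatty acid oxidation, median -0.25 with 5 of 31 lower and 11 over the list alone (adjusted p = 0.191 with an estimated correlation). Oxidative phosphorylation had a median of -0.13 with 0 of 54 passing (adjusted p = 0.122 with an estimated correlation). Interferon-stimulated genes had 9 of 29 lower and a median of -0.33, among them the T cell attractant Cxcl9 at -1.35 ± 0.18 and the GTPase gene Igtp at -1.24 ± 0.17 (adjusted p = 0.209 with an estimated correlation). Cell cycle genes had a median of -0.30 with Rrm2 lower (adjusted p = 0.446 with an estimated correlation). Clock genes had a median of -0.60 with 3 of 15 lower and the activator Npas2 higher at 0.90 ± 0.19 (adjusted p = 0.386 with an estimated correlation). Camera did not pass for the remaining lists. TGF-beta genes had a median of 0.12 with Ccn2 at 1.13 ± 0.19, Inhba at 0.95 ± 0.27 and Ltbp1 at -0.97 ± 0.19. Adult myocyte genes had a median of -0.08 with the potassium channel Kcnd2 at -0.64 ± 0.14, and lymphocyte and granulocyte genes a median of 0.28 with 0 of 10 passing. The endothelial median was -0.07 and its mean near 0, with camera on the higher side and Sox18 at 0.55 ± 0.13. Arterial and endocardial genes had a median of -0.05 with Depp1 at -1.36 ± 0.33, and smooth muscle genes 0.13 with Smtn at -0.57 ± 0.11. The adipocyte median of -0.01 and mean of 0.09 differed in sign, with Scd1 at 1.01 ± 0.17. So did the glycolysis median of -0.09 and mean of 0.07, with Pfkp at 1.25 ± 0.17, Pgam1 at 1.09 ± 0.14 and Pfkm at -0.38 ± 0.09. Atrial genes had a median of 0.17 with Dkk3 at 1.85 ± 0.34, and neural crest genes 0.37 with Pmp22 at 0.57 ± 0.12. Renin-angiotensin genes had a median of -0.11 with Mas1 lower, vascular growth factor genes -0.02 with Igf1 at 0.92 ± 0.20, immediate-early genes -0.14 with Hspb1 at 0.62 ± 0.17, and the genes next to Bmx 0.07 with 0 of 13 passing.

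**Figure D1:**
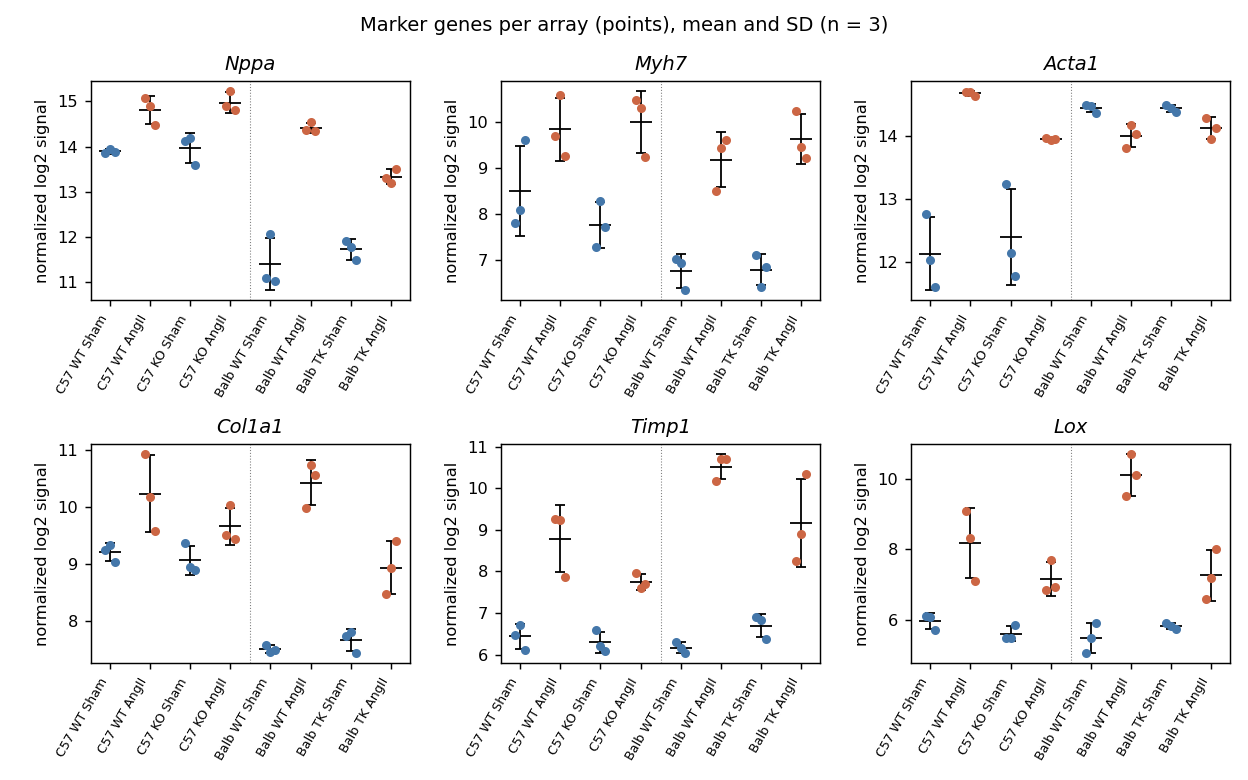
Normalized log2 signal of Nppa, Myh7, Acta1, Col1a1, Timp1 and Lox on the vertical axis in the 8 groups (points are arrays, bars mean and SD, n = 3). Within Balb/C, Lox reached 10.11 in wild type after AngII and 7.26 in the deficient mice. Within C57Bl/6J, Acta1 rose from 12.14 to 14.67 in wild type.

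With limma, 855 of 10816 genes passed in this comparison, 396 higher and 459 lower, 156 of them at least 2-fold, and 2608 had an unadjusted p below 0.05. The groups did not overlap in 29.2% of genes, where 10% is the share by chance. The count was 487 when arrays were scaled to a common median, and 1303 counted as probes. It was 545 and 455 without replicates 1 and 2 of AngII, and 503 and 492 without replicates 1 and 3 of sham. Of 67 named genes that passed, 47 kept their call under every alternative setting that tested them and 39 also without each array.

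Next came the same treatment in Bmx-deficient C57Bl/6J mice, AngII against sham. Myh7 rose by 2.23 ± 0.48, the matrix gene Spon2 by 2.23 ± 0.46, Acta1 by 1.56 ± 0.32, Nppa by 1.01 ± 0.19 and Nppb by 0.96 ± 0.12. Clock genes were among the largest changes: the repressors Ciart at -3.41 ± 0.71 and Per3 at -2.01 ± 0.40 and the output gene Dbp at -2.32 ± 0.46 fell, and Arntl, the activator of the clock, rose by 1.74 ± 0.34. Col3a1 rose by 1.51 ± 0.31, Mfap5 by 1.49 ± 0.30, Timp1 by 1.46 ± 0.31, Ccn2, a matricellular target of TGF-beta, by 1.25 ± 0.19, and Lox by 1.55 ± 0.38. The call of Lox was lost without background correction (adjusted p = 0.0955), with the authors' values (adjusted p = 0.0937), without the dim filter (adjusted p = 0.0668) and with replicate numbers as a block (adjusted p = 0.0538), and that of Acta1 with only the 6 arrays (adjusted p = 0.0503). With 1 of the 6 arrays left out, Lox and Timp1 lost their calls in 6 runs, Acta1 in 5, Myh7 and Col3a1 in 4 and Nppa in 2. Col1a1 stood at 0.60 ± 0.28 (adjusted p = 0.234). Lypd2 at -1.42 ± 0.20, Ano10 at -1.25 ± 0.16, Ky at -1.21 ± 0.14, the protease gene Adamts7 at -1.16 ± 0.18 and the anion transporter Slc26a6 at -1.04 ± 0.17 fell. So did the water channel Aqp4 at -1.13 ± 0.27 and the clock-related factor Tef at -1.11 ± 0.28.

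Hypertrophy genes had a median of 0.55 with 7 of 15 higher, among them Xirp2 at 1.49 ± 0.19. Macrophage markers had 9 of 33 higher and a median of 0.52. Adgre1, the F4/80 antigen gene, stood at 0.96 ± 0.13 and lysozyme Lyz2 at 0.95 ± 0.17. Both lists had an adjusted p of 0.0967 with an estimated correlation. Of the matrix genes 11 of 47 rose, 26 over the list alone, with a median of 0.65 (adjusted p = 0.378 with an estimated correlation). Lymphocyte and granulocyte genes had a median of 0.46 with 0 passing, and the neutrophil gene S100a8 at 2.30 ± 0.65 (adjusted p = 0.0699), while 2 passed over the list alone (adjusted p = 0.378 with an estimated correlation). Fibroblast markers had a median of 0.18, with Islr at 0.93 ± 0.16 and Medag at 0.89 ± 0.15. Clock genes had 6 of 15 lower and 1 higher, with a median of -0.87, and cell cycle genes a median of -0.36 with 0 passing. The adjusted p was 0.378 for each of these with an estimated correlation. The IL-6 and STAT3 list had a median of 0.10 and camera did not pass, with Serpina3n at 0.90 ± 0.17 and Socs3 at 0.65 ± 0.14 among 3 that rose. Slc4a1 rose by 1.91 ± 0.39 and Dkk3 by 1.39 ± 0.34, Tbx5 fell at -0.73 ± 0.18, and in fatty acid oxidation Crat fell at -0.56 ± 0.10 and Acads at -0.44 ± 0.09, with a list median of -0.09.

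In this comparison 402 genes passed with limma, 221 higher and 181 lower, 50 at least 2-fold, with 2348 below an unadjusted p of 0.05 and 26.7% of genes without overlap. Median scaling gave 332 genes with 289 higher and 43 lower. The count was 253 with replicate numbers as a block, 207 from the 6 arrays alone, 678 with a larger offset, 689 as probes, 713 without background correction, 709 with the authors' values and 754 with a trended prior. Without 1 array it was 175, 196 and 76 for AngII replicates 1, 2 and 3, and 149, 172 and 45 for sham replicates 1, 2 and 3. Of 41 named genes that passed, 10 kept their call under every alternative and without each array, which were Xirp2, Lypd2, Ano10, Ky, Adamts7, Slc26a6, Nppb, Ccn2, Rcan1 and Adgre1.

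Across genotypes of C57Bl/6J, 87 genes rose in both and 83 fell in both, against 8.09 and 7.68 expected from the counts (Fisher p = 1.37e-68 and 1.96e-66). Of the 855 genes of wild type, 780 (91.2%) had the same direction in the deficient mice, and the responses correlated at r = 0.57 with a slope of 0.51. Genes are not independent replicates. The slope, over genes called in wild type, is lowered by that choice and does not compare sizes.

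Whether genotype mattered at baseline was asked in sham mice of C57Bl/6J, deficient against wild type. The brightest myocyte genes hardly differed, with Nppa at 0.07 ± 0.19 (adjusted p = 0.978) and Atp2a2, the calcium pump of the reticulum, at 0.00 (adjusted p = 0.996). Smallest p-values belonged to the semaphorin receptor Plxnb1 at 0.71 ± 0.13, Arf6 at 0.49 ± 0.09, Frs3, Dppa5a at 0.46 ± 0.09 and Ciao3 at 0.53 ± 0.11, each with an adjusted p of 0.415. Adjusted over their lists alone, the lipase inhibitor Angptl4 passed at -1.49 (adjusted p = 0.0108 among vascular growth factors) and Vegfd, the gene beside Bmx, at -1.28 (adjusted p = 0.00634 among the neighbours of Bmx), and both were chosen after their values were seen. Macrophage markers had a median of -0.18, cell cycle genes -0.18 and interferon-stimulated genes -0.19, with 0 genes passing in each. The adjusted p was 0.537 for each with an estimated correlation. Clock genes had a median of 0.39 and Dbp stood at 0.74 ± 0.46 (adjusted p = 0.851). No gene passed with limma (0 of 10816, smallest adjusted p = 0.415), while 718 had an unadjusted p below 0.05, and 1 probe passed when all detected probes were tested. Camera passed for 3 lists at the preset correlation, and fry for 0. The groups did not overlap in 10.9% of genes.

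Under AngII, the deficient C57Bl/6J mice were set against wild type. Wdfy1, an endosomal adaptor gene, was higher by 2.11 ± 0.11 in the deficient mice and the endosomal GTPase Rab4a by 1.43 ± 0.12, while Plac9a stood at -2.41 ± 0.18, Serpina3n at -1.83 ± 0.17 and Tmem254a at -1.62 ± 0.18. Mmrn1 was lower by at least 3.09-fold. The calls of these 6 genes held under every setting and without each array, except that Mmrn1 was not tested when a wild type AngII array was left out. The wild type AngII group stood apart from the other 3 groups: Wdfy1 read 6.33 ± 0.12 there and 8.44 ± 0.15 in deficient AngII mice, and Plac9a 8.75 ± 0.31 and 6.33 ± 0.29 (mean ± SD). Smaller differences passed for the kinase Pim3 at 1.04 ± 0.18, Lgr6 at 0.74 ± 0.13, Tnfaip8 at 0.55 ± 0.09, and Cited2 at 0.75 ± 0.13, all higher. Lower were Tmem181a at -0.93 ± 0.12, Pisd-ps3 at -1.51 ± 0.25, Tmem267 at -1.08 ± 0.15, the cyclin Ccnk at -0.80 ± 0.13, Ide, the insulin-degrading enzyme, at -0.79 ± 0.11 and Entpd4 at -0.73 ± 0.10. Of 12 alternatives and 6 runs without 1 array, the call was lost in 6 and 6 for Cited2, 4 and 6 for Tnfaip8, 5 and 5 for Pim3, Lgr6 and Ccnk, 3 and 4 for Pisd-ps3, 2 and 2 for Entpd4, 1 and 1 for Tmem267, 3 and 0 for Ide and 2 and 0 for Tmem181a. Markers of hypertrophy did not pass: Nppa 0.16 ± 0.19 (adjusted p = 0.827), Nppb -0.40 ± 0.12 (adjusted p = 0.291), and Acta1 -0.72 ± 0.32 (adjusted p = 0.502). Nor did Myh7 at 0.16 ± 0.48 (adjusted p = 0.938), Timp1 at -1.04 ± 0.31 (adjusted p = 0.304) and Col1a1 at -0.57 ± 0.28 (adjusted p = 0.53).

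List medians in the deficient AngII mice were -0.29 for matrix genes, with 0 of 47 passing, and -0.11 for endothelial genes. The adjusted p was 0.477 for both with an estimated correlation. Hypertrophy genes stood at -0.24 and the IL-6 and STAT3 list at -0.14, with Serpina3n alone passing. For both it was 0.441 with an estimated correlation. Vegfd stood at -1.03 (adjusted p = 0.236 over all genes, 0.0331 over the neighbours of Bmx), a gene chosen after its values were seen. With limma 18 genes passed, 6 higher and 12 lower, 10 at least 2-fold, and 1047 had an unadjusted p below 0.05, with 14.8% of genes without overlap. Median scaling gave 16 genes with 9 higher and 7 lower. The count was 9 without AngII replicate 2 of wild type and 11 without AngII replicate 1 of the deficient mice. It was 7 from the 6 arrays alone, 11 with replicate numbers as a block, 31 without background correction, 32 with a larger offset, 38 with a trended prior and 29 with the authors' values.

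**Figure D2:**
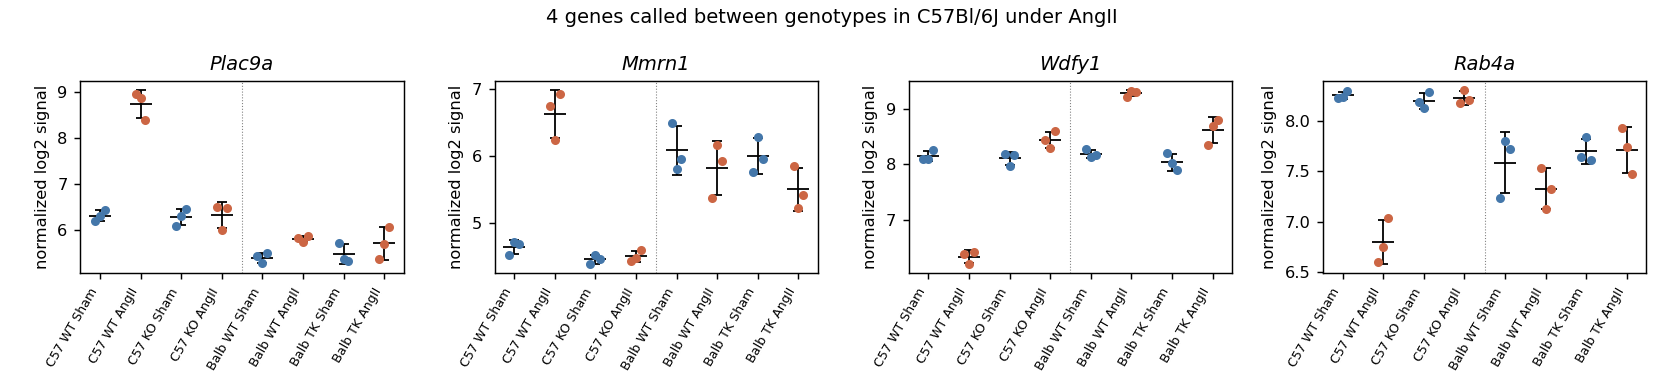
Normalized log2 signal of Plac9a, Mmrn1, Wdfy1 and Rab4a on the vertical axis in the 4 C57Bl/6J groups and the 4 Balb/C groups (points are arrays, bars mean and SD, n = 3). In C57Bl/6J wild type after AngII, Plac9a read 8.75 and Mmrn1 6.63 against at most 6.33 and 4.64 in the other 3 groups.

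The difference of AngII responses between the genotypes of C57Bl/6J was tested directly. It passed for Wdfy1 at 2.16 ± 0.16, Rab4a at 1.49 ± 0.16, Plac9a at -2.39 ± 0.25 and the membrane protein gene Tmem267 at -1.55 ± 0.22. Mmrn1 passed too (adjusted p = 0.00205), with 3 of the 4 groups at background. Hypertrophy and matrix markers did not differ past the threshold, with Acta1 at -0.98 ± 0.46 (adjusted p = 0.557), and Timp1 at -0.89 ± 0.44 (adjusted p = 0.584). Nor did Myh7 at 0.90 ± 0.68 (adjusted p = 0.75), Nppb at -0.32 ± 0.17 (adjusted p = 0.602) and Nppa at 0.09 ± 0.26 (adjusted p = 0.951). Median differences were -0.31 for the IL-6 and STAT3 list, -0.29 for hypertrophy genes and -0.18 for matrix genes (adjusted p = 0.172, 0.326 and 0.767 with an estimated correlation). Fry passed for 0 lists. With limma 6 genes passed, 2 higher and 4 lower, and 972 had an unadjusted p below 0.05. Counts of 11 to 17 came from a stricter filter (11), a trended prior (12), the mean of detected probes (12), array weights (13), a larger offset (14), no background correction (14) and the authors' values (17). The median of all genes was 0.133 under median scaling. Wdfy1, Rab4a and Plac9a kept their calls throughout, Mmrn1 kept its call in the 9 of 12 left-out runs that tested it, while Tmem267 lost its call without background correction, with the authors' values and without each of 5 arrays.

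In Balb/C wild type mice the same comparison of AngII with sham was made. Lox rose by 4.62 ± 0.32, Timp1 by 4.35 ± 0.35, the cartilage matrix gene Comp 18.4-fold and Dkk3 by 3.91 ± 0.23. So did Mfap5 by 3.69 ± 0.22, Col8a1 by 3.47 ± 0.24, Mfap4 by 3.36 ± 0.30, Col3a1 by 3.36 ± 0.22 and Col1a1 by 2.93 ± 0.22. The secreted peptide gene Ecrg4 rose at least 13.7-fold and Postn, a matricellular protein of activated fibroblasts, at least 2.59-fold. Xirp2, an actin-binding gene of the intercalated disc, rose by 3.48 ± 0.22, Nppa by 3.01 ± 0.22, Myh7 by 2.41 ± 0.29, Ccn2 by 2.00 ± 0.22 and Nppb by 0.98 ± 0.21. On all 3 AngII arrays Nppb was the second brightest probe and quantile normalization gave it the value 14.65, which limits the rise that this normalization can show. Acta1 fell at -0.44 ± 0.14, a call lost under median scaling (adjusted p = 0.314) and without each of 3 of the 6 arrays. Myh6 stood at -0.05 ± 0.13 (adjusted p = 0.795). Genes that fell most were the lipase Ces1d at -2.55 ± 0.41, Pigh at -2.41 ± 0.32, the potassium channel subunit Kcnv2 at -2.21 ± 0.25, Ky at -2.20 ± 0.28, Lgals4 at -2.20 ± 0.24 and Ybx2 at -1.89 ± 0.25. Also among the lowest were the thioesterase Acot1 at -1.91 ± 0.29, Pdk4, a brake on glucose oxidation, at -1.89 ± 0.48, Fbp2 at -1.86 ± 0.34 and Dgat2, a triglyceride synthesis enzyme, at -1.86 ± 0.22.

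Of the matrix genes 43 of 50 rose and 0 fell, with a median of 1.52. Hypertrophy genes had 12 of 15 higher and a median of 1.18. Macrophage markers had 25 of 32 higher and a median of 1.11, with Ms4a7 at 2.66 ± 0.24 and Adgre1 at least 4.31-fold. Each of these lists had an adjusted p of 0.178 with an estimated correlation. Cell cycle genes had 17 of 24 higher and a median of 1.00, among them the spindle gene Prc1 at 2.02 ± 0.38 and the mitotic gene Nusap1 at 1.69 ± 0.28. The growth factor gene Tgfb2 stood at 2.66 ± 0.29, with 12 of 23 TGF-beta genes higher, 3 lower and a median of 0.47. Both lists had an adjusted p of 0.333 with an estimated correlation. IL-6 and STAT3 genes had 11 of 22 higher and a median of 0.66, with Serpina3n at 2.34 ± 0.28 (adjusted p = 0.178 with an estimated correlation). Fibroblast markers had 12 of 20 higher and 2 lower, a median of 0.75 and Mgp, an inhibitor of calcification, at 2.60 ± 0.18 (adjusted p = 0.323 with an estimated correlation). Immediate-early genes had 16 of 29 higher and a median of 0.66, with Egr2 at 2.70 ± 0.25 and the heat shock gene Hspa1a at 2.66 ± 0.50 (adjusted p = 0.178 with an estimated correlation). Fatty acid oxidation genes fell in 21 of 31 cases and rose in 2, with a median of -0.82 and Acaa2 at -1.57 ± 0.24 (adjusted p = 0.325 with an estimated correlation).

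Camera did not pass for the other lists of this comparison. Endothelial genes had 12 of 27 lower, among them the junction gene Cldn5 at -1.10 ± 0.15 and Tie1 at -1.03 ± 0.17, and 4 higher, with a median of -0.33. Smooth muscle genes had 7 of 21 lower, Smtn at -1.38 ± 0.15 and the channel gene Kcnj8 at -1.32 ± 0.17, with a median of -0.21. Oxidative phosphorylation genes had 7 higher and 12 lower of 56, with Sdhd at 1.40 ± 0.20, Cox7a1 at -1.12 ± 0.17 and a median of -0.17. Clock genes had 5 of 13 higher and a median of 0.19, the repressors Per2 at 2.24 ± 0.36 and Bhlhe40 at 2.02 ± 0.21.

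With limma 3972 of 10669 genes passed here, 1895 higher and 2077 lower, 854 at least 2-fold, and 4892 had an unadjusted p below 0.05. The groups did not overlap in 46.5% of genes. Of 4088 genes with several detected probes, 132 had called probes of opposite direction, against 1 of 4259 in C57Bl/6J wild type. A call can thus depend on the probe. Under median scaling 4089 passed with 3804 higher and 285 lower, and the median of all genes was 0.322, so the balance of higher and lower genes depended on the normalization. Of 104 named genes that passed, 88 kept their call under every alternative that tested them, 87 of them also without each array, and 6791 probes passed when all were counted.

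**Figure D3:**
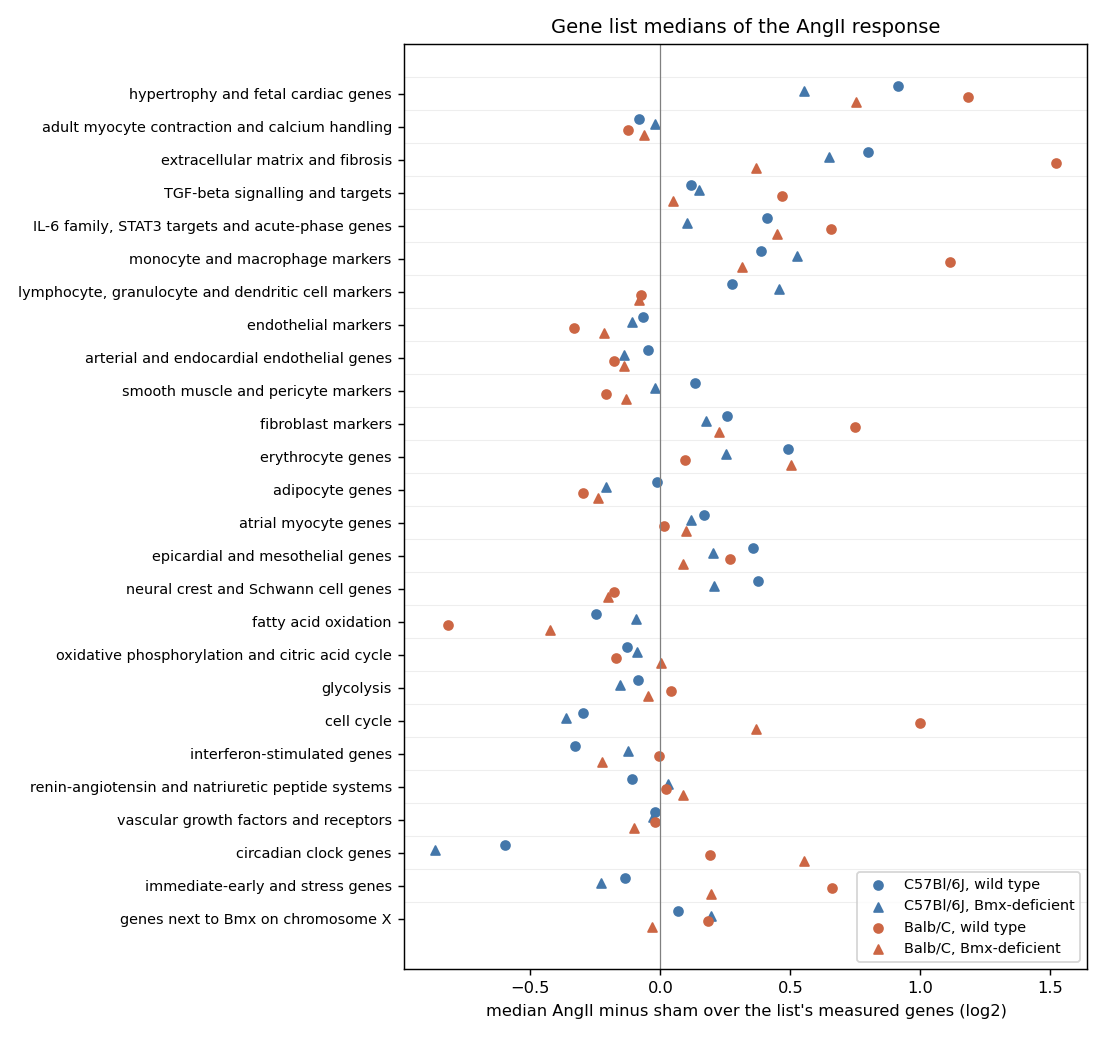
Median log2 difference between AngII and sham on the horizontal axis for 26 gene lists, with 1 point for each genotype of C57Bl/6J and Balb/C. The matrix list stood at 1.52 in Balb/C wild type and 0.37 in Balb/C deficient mice, against 0.80 and 0.65 in C57Bl/6J, and all genes moved by 0.322 in Balb/C wild type under median scaling.

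Bmx-deficient Balb/C mice were compared in the same way. Myh7 rose by 2.83 ± 0.29, the globin gene Hbb-b2 by 2.75 ± 0.32, Timp1 by 2.46 ± 0.35, the clock repressors Per2 by 2.19 ± 0.36 and Ciart by 1.95 ± 0.32, and Xirp2 by 1.94 ± 0.22. Nppa rose by 1.61 ± 0.22, Col3a1 by 1.63 ± 0.22, Col1a1 by 1.28 ± 0.22 and Ccn2 by 0.97 ± 0.22. Also among the largest rises were the respiratory subunit Ndufb9 at 2.04 ± 0.30, the translation factor Pabpc1 at 2.00 ± 0.18, Arpc2 at 1.94 ± 0.18 and Polr2g at 1.92 ± 0.26. Lox rose by 1.43 ± 0.32, a call lost without background correction (adjusted p = 0.0608) and with the authors' values (adjusted p = 0.0588). Nppb stood at 0.65 ± 0.21 (adjusted p = 0.0553), and Acta1 at -0.31 ± 0.14 (adjusted p = 0.141), while Postn, at background in sham, did not pass (adjusted p = 0.107). Array weights brought calls for Nppb (adjusted p = 0.0122), Acta1 (adjusted p = 0.0281) and Postn (adjusted p = 0.0317), and a trended prior for Nppb (adjusted p = 0.0417). Pdk4 fell at -2.24 ± 0.48, the lipogenic gene Thrsp at -1.63 ± 0.32, Ces1d at -1.59 ± 0.41, and Inmt at -1.55 ± 0.47. So did Angptl4 at -1.38 ± 0.41, Fads6 at -1.37 ± 0.20, the ubiquitin ligase Fbxo32 at -1.24 ± 0.30 and Prr29 at -1.18 ± 0.18, and Cib3 fell by at least 3.28-fold.

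Matrix genes had 15 of 50 higher and a median of 0.37, and hypertrophy genes 7 of 15 higher and a median of 0.75 (adjusted p = 0.473 and 0.218 with an estimated correlation). Red cell genes had a median of 0.50 with Alas2, the heme synthesis enzyme, at 1.51 ± 0.21. Atrial genes had a median of 0.10 with Dkk3 at 1.77 ± 0.23 and Pam at 1.06 ± 0.12. Both had an adjusted p of 0.205 with an estimated correlation. Clock genes had 4 higher and 1 lower of 13 with a median of 0.55. IL-6 and STAT3 genes had 6 of 22 higher with a median of 0.45. For both it was 0.218 with an estimated correlation. Macrophage markers had 8 of 32 higher with a median of 0.31, among them Pf4 at 1.51 ± 0.24 and Lyve1, a marker of resident macrophages, at 1.39 ± 0.23 (adjusted p = 0.473 with an estimated correlation). Immediate-early genes had a median of 0.19 with Egr3 at 1.59 ± 0.28 and Ccn1 at -1.17 ± 0.29 (adjusted p = 0.218 with an estimated correlation). Fatty acid oxidation genes fell in 11 of 31 cases with a median of -0.43 (adjusted p = 0.606 with an estimated correlation). Endothelial genes had 7 of 27 lower, such as the apelin receptor Aplnr at -1.08 ± 0.25 and Cdh5 at -0.70 ± 0.20, with a median of -0.22, and camera did not pass.

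Limma passed 1431 genes, 790 higher and 641 lower, 252 at least 2-fold, with 3044 below an unadjusted p of 0.05 and 34.8% of genes without overlap. Median scaling gave 664 with 540 higher and 124 lower, array weights gave 2416, and 2652 probes passed. Without AngII replicate 3 of the deficient mice the count was 700, and without their sham replicate 3 it was 767. Of 82 named genes that passed, 46 kept their call under every alternative and without each array.

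Between the genotypes of Balb/C, 700 genes rose in both and 482 fell in both, against 140 and 125 expected (Fisher p = 3.56e-222 for the lower genes). The same direction held for 3632 of 3972 genes (91.4%), with r = 0.74. The slope was 0.48, with the same limit, and genes are not independent replicates.

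In sham mice of Balb/C, deficient against wild type, 0 of 10669 genes passed with limma (smallest adjusted p = 0.361). Ccn2 stood at -0.01 ± 0.22 (adjusted p = 0.989), Nppa at 0.32 ± 0.22 (adjusted p = 0.601) and Acta1 at -0.01 ± 0.14 (adjusted p = 0.986). Smallest p-values were those of Trappc2 at 0.78 ± 0.15, a vesicle transport gene near Bmx, the coactivator Crtc2, the antiviral gene Mx2 at -0.73 ± 0.16, Ccdc160 and Mtx2 at 0.62 ± 0.14. Macrophage markers had a median of 0.29 with 0 passing over all genes and 3 over the list alone (adjusted p = 0.506 with an estimated correlation). Those 3 were the chemokines Ccl9 at 0.88 (adjusted p = 0.022) and Ccl6 at 0.62 (adjusted p = 0.0276) and the complement gene C1qc at 0.76 (adjusted p = 0.022), each over the list alone and chosen after the values were seen. Interferon genes had a median of -0.26 with Mx2 passing over the list alone (adjusted p = 0.00789), and adjusted p = 0.506 with an estimated correlation for the list. Trappc2 passed over the neighbours of Bmx alone (adjusted p = 0.00105). An unadjusted p below 0.05 was found for 1136 genes, fry passed for 0 lists, 16.7% of genes had no overlap, and the median of all genes was 0.104 under median scaling.

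Under AngII, Bmx-deficient Balb/C mice were set against wild type. Among the lower genes were the angiopoietin-like gene Angptl7 at -3.51 ± 0.29, Comp at -3.42 ± 0.34, Ecrg4 at -3.28 ± 0.19, Lox at -2.85 ± 0.32, and the growth factor Ptn at -2.64 ± 0.25. Also lower were Cthrc1 at -2.46 ± 0.22, the integrin-like gene Itgbl1 at -2.39 ± 0.17, Col3a1 at -1.93 ± 0.22, Col1a1 at -1.49 ± 0.22 and Postn at -1.42 ± 0.15. Col8a2 was lower by at least 5.97-fold and the transcription factor Zhx2 by at least 4.18-fold, and Ddah1, which clears an inhibitor of nitric oxide synthesis, stood at -2.62 ± 0.23. Ccn2 stood at -1.04 ± 0.22, Xirp2 at -1.74 ± 0.22 and Nppa at -1.08 ± 0.22. Nppb stood at -0.36 ± 0.21 (adjusted p = 0.305), limited by its wild type value near the top of the scale. Myh7 at 0.45 ± 0.29 (adjusted p = 0.358) and Acta1 at 0.12 ± 0.14 (adjusted p = 0.621) did not pass. Timp1 was lower at -1.36 ± 0.35, a call lost from the 6 arrays alone (adjusted p = 0.0574), without the dim filter (adjusted p = 0.0932) and without each of 4 arrays. Higher in the deficient mice were the potassium channel subunit Kcne1 at 2.33 ± 0.27, Tmprss13 at 1.87 ± 0.30, the gluconeogenic enzyme Fbp2 at 1.87 ± 0.34, and Snai3 at 1.84 ± 0.33. So were Ttll1 at 1.65 ± 0.31, Dhrs7c at 1.65 ± 0.27, Alkbh7 at 1.63 ± 0.22, Lamb3 at 1.63 ± 0.19, Adh1 at 1.60 ± 0.45 and Pigh at 1.50 ± 0.32.

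Of 50 matrix genes 42 were lower and 0 higher, with a median of -1.30 (adjusted p = 0.194 with an estimated correlation). TGF-beta genes had 9 of 23 lower and a median of -0.54, with Tgfb2 at -1.87 ± 0.29 and Tgfb3 at -1.44 ± 0.17. Fibroblast markers had 8 lower and 1 higher of 20, a median of -0.49, Pi16 at -1.20 ± 0.20 and Gsn at 1.14 ± 0.22. Cell cycle genes had 16 of 24 lower and a median of -0.93, with Prc1 at -2.08 ± 0.38. From TGF-beta on, each had an adjusted p of 0.249 with an estimated correlation. Interferon genes had 11 of 25 lower and a median of -0.49, with Usp18 at -1.01 ± 0.18 (adjusted p = 0.194 with an estimated correlation). Hypertrophy genes had 6 of 15 lower and a median of -0.36 (adjusted p = 0.279 with an estimated correlation). Macrophage markers had 5 of 32 lower and a median of -0.36, and immediate-early genes 3 of 29 lower and -0.31 (adjusted p = 0.466 and 0.249 with an estimated correlation). Fatty acid oxidation genes were higher in 10 of 31 cases with a median of 0.42, among them Acaa2 at 1.33 ± 0.24 and Decr1 at 0.95 ± 0.17 (adjusted p = 0.249 with an estimated correlation). Oxidative phosphorylation genes were higher in 4 of 56 with 0.32 (adjusted p = 0.278 with an estimated correlation). Adult myocyte genes had a median of 0.09 with Tnni3 at 0.69 ± 0.14 (adjusted p = 0.279 with an estimated correlation). Smooth muscle genes had 6 of 21 higher, with the actin Acta2 at 0.91 ± 0.21, and a median of 0.19 that turned to -0.10 under median scaling (adjusted p = 0.194 with an estimated correlation).

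With limma 1146 genes passed, 421 higher and 725 lower, 279 at least 2-fold, with 2774 below an unadjusted p of 0.05 and 29.2% of genes without overlap. Under median scaling 2153 passed with 106 higher and 2047 lower, and the median of all genes was -0.256. Array weights gave 2040. Without wild type AngII replicates 2 and 3 the count was 473 and 633, and without AngII replicates 1 and 2 of the deficient mice 518 and 703. Of 92 named genes that passed, 54 kept their call under every alternative that tested them and without each array.

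The test of the difference of AngII responses was also run between the genotypes of Balb/C. Lox at -3.19 ± 0.45, Angptl7 at -3.18 ± 0.42, Comp at -3.17 ± 0.48, and Ptn at -2.90 ± 0.35 responded less in the deficient mice. So did the receptor-like gene Pdgfrl at -2.58 ± 0.28, Mfap5 at -2.53 ± 0.32, Ddah1 at -2.48 ± 0.33, Col3a1 at -1.73 ± 0.31 and Col1a1 at -1.65 ± 0.31. Ecrg4 (adjusted p = 7.15e-06), Col8a2 (adjusted p = 5.78e-05), Cthrc1 (adjusted p = 0.000489) and Postn (adjusted p = 0.00225) passed in the same direction, with both sham groups at background. Nppa differed by -1.40 ± 0.31, a call lost with the authors' values (adjusted p = 0.0519), without the dim filter (adjusted p = 0.101) and without each of 8 arrays. Timp1 at -1.89 ± 0.50 (adjusted p = 0.0621), Ccn2 at -1.03 ± 0.32 (adjusted p = 0.114), Nppb at -0.34 ± 0.30 (adjusted p = 0.653, also limited), Myh7 at 0.42 ± 0.42 (adjusted p = 0.69) and Acta1 at 0.13 ± 0.19 (adjusted p = 0.809, limited by its sham signals) did not pass. Timp1 passed under median scaling (adjusted p = 0.00665), with a trended prior (adjusted p = 0.0478) and with array weights (adjusted p = 0.00526), and Ccn2 under median scaling (adjusted p = 0.0222), while Col1a1 lost its call without the dim filter (adjusted p = 0.0564). Positive differences were found for Kcne1 at 1.79 ± 0.38, Ky at 1.71 ± 0.40, the adhesion gene Cntn2 at 1.65 ± 0.34, and Alkbh7 at 1.47 ± 0.31. The same held for Dpysl4 at 1.47 ± 0.28, the aminotransferase Gpt at 1.46 ± 0.28, the calcium channel subunit Cacnb2 at 1.38 ± 0.31, Ephb1 at 1.36 ± 0.29, Lamb3 at 1.35 ± 0.27 and Itgb6 at 1.34 ± 0.24. Kept under every alternative and without each array were Ecrg4, Lox, Angptl7, Comp, Ptn, Pdgfrl, Mfap5, Ddah1, Cthrc1, Col3a1, Postn, Tgfb3, Mgp and Dkk3, 14 of 46. Col8a2 kept its call in the 9 of 12 left-out runs that tested it.

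Matrix genes passed in 24 of 50 cases, 40 over the list alone, and all of these were lower, with a median of -1.23 (adjusted p = 0.18 with an estimated correlation). Macrophage markers had a median of -0.67 with Ms4a7 at -1.36 ± 0.34, and fibroblast markers -0.47 with Mgp at -1.47 ± 0.26. Both had an adjusted p of 0.274 with an estimated correlation. Cell cycle genes had a median of -0.58 with 0 passing, and TGF-beta genes -0.46 with Tgfb3 at -1.54 ± 0.23. Hypertrophy genes had a median of -0.45. IL-6 and STAT3 genes had -0.29 with the cytokine signalling inhibitor Socs2 at -0.98 ± 0.22. From cell cycle on, each had an adjusted p of 0.283 with an estimated correlation. Immediate-early genes had a median of -0.45 with Egr2 at -1.91 ± 0.36 (adjusted p = 0.18 with an estimated correlation). Interferon genes had a median of -0.29 (adjusted p = 0.299 with an estimated correlation). Positive medians were found for red cell genes at 0.46 with Alas2 at 1.31 ± 0.29 and fatty acid oxidation at 0.40 with Crat at 0.80 ± 0.18 (adjusted p = 0.213 and 0.283 with an estimated correlation).

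Here limma passed 225 genes, 61 higher and 164 lower, 168 at least 2-fold, with 1572 below an unadjusted p of 0.05. Median scaling gave 766 with 3 higher and 763 lower, and the median of all genes was -0.385. No filter gave 110 and array weights 720. Without wild type AngII replicates 1, 2 and 3 the count was 470, 90 and 74, and without AngII replicates 1 and 2 of the deficient mice 92 and 147. Without their sham replicates 1 and 2 it was 140 and 128, and without wild type sham replicate 1 it was 118.

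**Figure D4:**
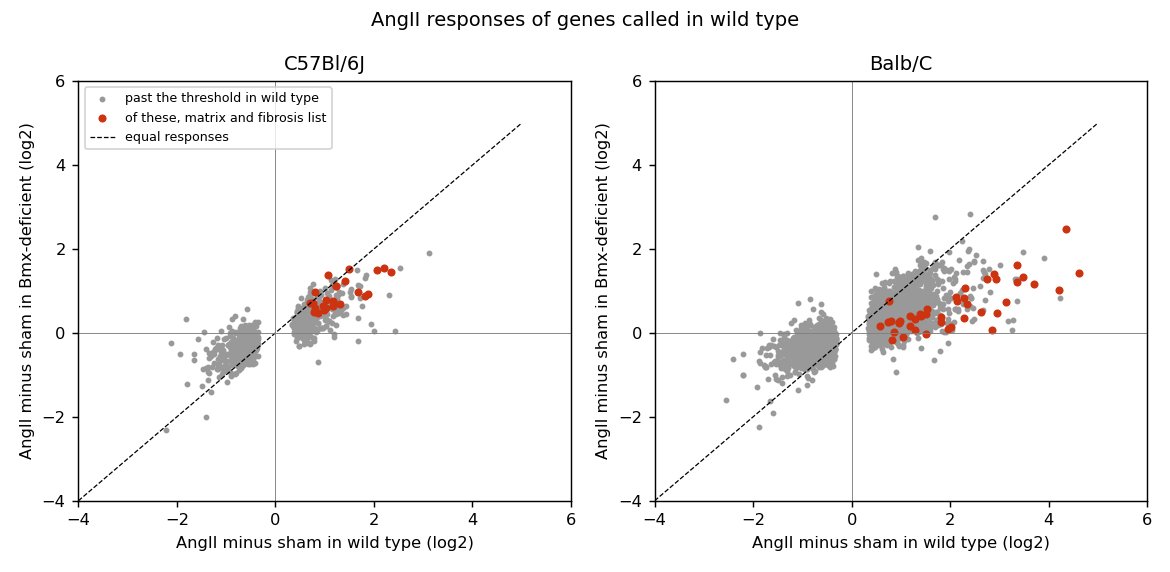
AngII response (log2) of wild type mice on the horizontal axis and of Bmx-deficient mice on the vertical axis, for genes that passed in wild type of C57Bl/6J and Balb/C, with matrix genes in red and a dashed line where both are equal (means of n = 3 arrays per group). Nearly all Balb/C matrix genes lie below the line, a side that choosing genes by their wild type response favours, with a median difference of responses of -1.23, against -0.18 in C57Bl/6J.

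Between strains, the difference of the AngII responses was tested in wild type mice with all 24 arrays in 1 fit. Larger in Balb/C were the responses of Ecrg4 (adjusted p = 7.49e-07), Ccn4, a Wnt-induced matricellular gene, by 3.46 ± 0.38, Ptn by 3.04 ± 0.45, Pdgfrl by 2.75 ± 0.29 and Col3a1 by 2.67 ± 0.31. Clock genes Dbp at 3.17 ± 0.69, Ciart at 3.06 ± 0.74 and Per2 at 2.80 ± 0.87 had estimates of opposite sign. AngII and sham arrays overlapped for Per2 in C57Bl/6J and Dbp in Balb/C, so opposite responses were not shown there. Wdfy1 at 2.88 ± 0.17 had responses of opposite sign, and the histone gene H2ac22 differed by 2.54 ± 0.55. Signed responses were lower in Balb/C for Slc4a1 at -2.38 ± 0.63, Mmrn1 (adjusted p = 0.000149) and Plac9a at -1.98 ± 0.25. The same held for Pdk4 at -1.96 ± 0.62, Tmprss13 at -1.91 ± 0.44, Pigh at -1.90 ± 0.47, Kcne1 at -1.71 ± 0.38, Dgat2 at -1.69 ± 0.27 and Gsn, an actin-severing gene, at -1.60 ± 0.30. Estimates of the genes from Pdk4 on were negative in Balb/C. For Pdk4, Tmprss13, Pigh and Dgat2 the estimated fall was larger in Balb/C, such as -2.40 against -0.50 for Pigh. Ciart, Slc4a1 and Pdk4 lost their calls in 2 of 7 alternatives and Per2 in 1. Acta1 differed by -2.99 ± 0.35, but its Balb/C sham signal lay 0.283 below the top of the normalized scale, so a rise like that of C57Bl/6J could not have shown. List differences were 0.93 for matrix genes, 1.02 for cell cycle and 0.84 for macrophage markers. They were 1.53 for clock genes, 0.81 for immediate-early genes, 0.43 for TGF-beta genes and 0.43 for interferon genes. The adjusted p was 0.239 for each of these with an estimated correlation. Lower in Balb/C were fatty acid oxidation at -0.48 and smooth muscle at -0.33 (adjusted p = 0.374 and 0.239 with an estimated correlation). With limma 1543 of 9921 genes passed, 839 higher and 704 lower in Balb/C, with 3076 below an unadjusted p of 0.05. Median scaling gave 2442 with 2401 higher and 41 lower, and a median of all genes of 0.407. Levels were not compared between the strains.

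The same difference between strains, with the same limit, was tested in Bmx-deficient mice, where clock genes had the largest values. Ciart differed by 4.92 ± 0.74, Per2 by 4.66 ± 0.87, Dbp by 3.60 ± 0.69, Per3 by 2.54 ± 0.54, Per1 by 2.51 ± 0.62 and the repressor Nr1d2 by 1.93 ± 0.39, and Arntl by -2.37 ± 0.39. Csrnp1 at 1.98 ± 0.36 and the histone genes H2ac22 at 2.30 ± 0.55, H2ac7 at 2.08 ± 0.48 and H2ac24 at 1.99 ± 0.50 had higher signed responses in Balb/C. Their estimates were positive in Balb/C and negative in C57Bl/6J. Pdk4 at -3.10 ± 0.62, Spon2 at -2.74 ± 0.57, Angptl4 at -2.38 ± 0.59, and Cib3 (adjusted p = 0.0114) had lower signed responses in Balb/C. So did the matrix protease Mmp3 at -1.95 ± 0.43, Vgll3 at -1.95 ± 0.38, Fads6 at -1.70 ± 0.30 and the prostaglandin enzyme Hpgd at -1.67 ± 0.41. Estimates of these genes were negative in Balb/C and positive in C57Bl/6J, such as -2.25 and 0.85 for Pdk4. Of 7 alternatives, H2ac22 and H2ac24 lost their calls in 4, Angptl4 and Mmp3 in 3, H2ac7 and Per1 in 2 and Cib3 in 1, and Hpgd lost it in 2 of 6. Acta1 differed by -1.87 ± 0.35, with its Balb/C sham signal 0.293 below the top of the scale. Clock genes differed by a median of 1.65 and cell cycle genes by 0.65 (adjusted p = 0.094 and 0.482 with an estimated correlation). The matrix difference of -0.02 did not pass camera. With limma 138 genes passed, 88 higher and 50 lower, with 1717 below an unadjusted p of 0.05. Median scaling gave 20 with 9 higher and 11 lower and a median of all genes of -0.121, no filter gave 78 and array weights 648. Without AngII replicates 1 and 2 of the deficient C57Bl/6J mice the count was 55 and 68, and without their sham replicates 1 and 2 it was 77 and 52. Without AngII replicate 3 of the deficient Balb/C mice it was 59, and without their sham replicates 1 and 3 it was 227 and 42. The time of day at which tissue was taken was not given.

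**Figure D5:**
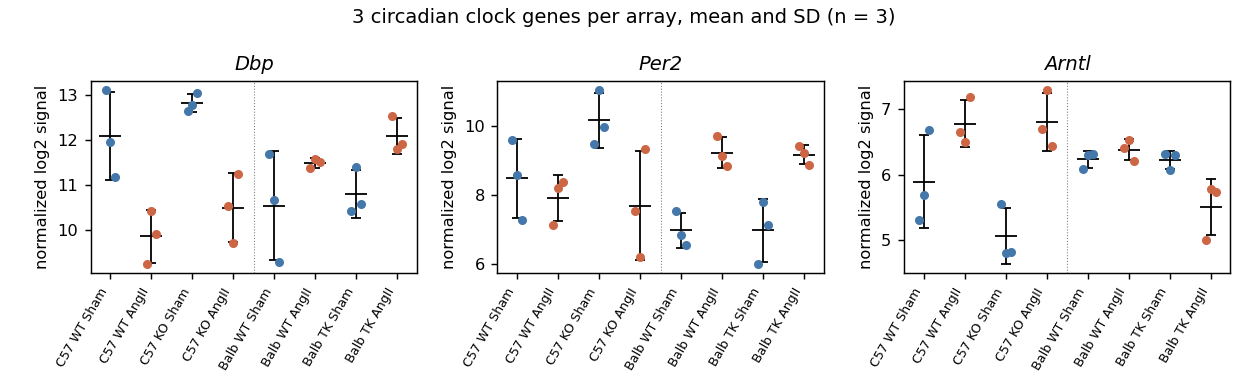
Normalized log2 signal of the clock genes Dbp, Per2 and Arntl on the vertical axis in the 8 groups (points are arrays, bars mean and SD, n = 3). Dbp read 12.82 in sham and 10.49 after AngII in C57Bl/6J deficient mice, and 10.79 and 12.08 in Balb/C deficient mice.

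The wild type responses of the strains shared 236 higher and 270 lower genes, against 68.0 and 90.5 expected (Fisher p = 5.44e-86 and 1.70e-81), with r = 0.51. Of 819 genes called in C57Bl/6J and measured in both, 708 (86.4%) had the same direction in Balb/C, and 21 were called in opposite directions. In the deficient mice 101 genes rose in both strains and 31 fell in both, against 16.6 and 11.1 expected (Fisher p = 3.88e-56 and 1.63e-07), with r = 0.38. For the genotype difference under AngII r was 0.25, with 3 genes higher in both strains against 0.25 expected (Fisher p = 0.0013), 2 lower in both against 0.807 expected (Fisher p = 0.191) and 1 called in opposite directions, and for the difference of responses r was 0.10 with 0 shared calls. Genes are not independent replicates in any of these counts.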

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

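Of the tests below, the splits of arrays were set before the results were seen, and the tests of the 3 patterns were chosen after. The values listed first are those for which a test of the difference itself passed, with limma for genes and camera at the preset correlation for lists.

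A test of the difference of AngII responses between the genotypes of C57Bl/6J passed for 6 genes. Responses higher in deficient C57Bl/6J mice were those of Wdfy1 at 2.16 and Rab4a at 1.49. Lower ones were those of Plac9a at -2.39 and Tmem267 at -1.55. The response was lower, with no size as groups lay at background, for Mmrn1 (adjusted p = 0.00205). Lists with a higher response had medians of 0.19 for fatty acid oxidation and 0.18 for interferon-stimulated genes. Lists with a lower response had medians of -0.29 for hypertrophy and fetal cardiac genes, -0.18 for extracellular matrix and fibrosis and -0.31 for IL-6 family and STAT3 genes. All 5 of these list calls were lost with an estimated correlation, and fry passed for 0 lists.

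A test of the difference of AngII responses between the genotypes of Balb/C passed for 225 genes. Responses higher in deficient Balb/C mice were those of Kcne1 at 1.79, Ky at 1.71, Cntn2 at 1.65, Alkbh7 at 1.47, Dpysl4 at 1.47, Gpt at 1.46, Cacnb2 at 1.38, Ephb1 at 1.36, Lamb3 at 1.35 and Itgb6 at 1.34. Lower ones were those of Lox at -3.19, Angptl7 at -3.18, Comp at -3.17, Ptn at -2.90, Pdgfrl at -2.58, Mfap5 at -2.53, Ddah1 at -2.48, Nppa at -1.40, Col1a1 at -1.65 and Col3a1 at -1.73. The response was lower, with no size as groups lay at background, for Ecrg4 (adjusted p = 7.15e-06), Col8a2 (adjusted p = 5.78e-05), Cthrc1 (adjusted p = 0.000489) and Postn (adjusted p = 0.00225). Lists with a higher response had medians of 0.12 for adult myocyte contraction and calcium handling, 0.13 for smooth muscle and pericyte markers, 0.46 for erythrocyte genes, 0.40 for fatty acid oxidation and 0.19 for oxidative phosphorylation and citric acid cycle. Lists with a lower response had medians of -0.45 for hypertrophy and fetal cardiac genes, -1.23 for extracellular matrix and fibrosis, -0.46 for TGF-beta signalling and targets, -0.29 for IL-6 family and STAT3 genes, -0.67 for monocyte and macrophage markers, -0.47 for fibroblast markers, -0.58 for cell cycle, -0.29 for interferon-stimulated genes and -0.45 for immediate-early and stress genes. All of these list calls were lost with an estimated correlation, and fry passed for 3 lists. Under median scaling the medians turned to -0.27 for smooth muscle, -0.08 for adult myocyte genes and -0.10 for oxidative phosphorylation.

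A test of the difference of AngII responses between the strains in wild type mice passed for 1543 genes. Strain and file could not be told apart. Responses higher in Balb/C wild type mice were those of Ccn4 at 3.46, Dbp at 3.17, Ciart at 3.06, Ptn at 3.04, Wdfy1 at 2.88, Per2 at 2.80, Pdgfrl at 2.75, Col3a1 at 2.67 and H2ac22 at 2.54. Lower ones were those of Acta1 at -2.99, Slc4a1 at -2.38, Plac9a at -1.98, Pdk4 at -1.96, Tmprss13 at -1.91, Pigh at -1.90, Kcne1 at -1.71, Dgat2 at -1.69 and Gsn at -1.60. With no size as groups lay at background, the response was higher for Ecrg4 (adjusted p = 7.49e-07) and lower for Mmrn1 (adjusted p = 0.000149). Lists with a higher response had medians of 0.93 for extracellular matrix and fibrosis, 0.43 for TGF-beta signalling and targets, 0.84 for monocyte and macrophage markers, 1.02 for cell cycle, 0.43 for interferon-stimulated genes, 1.53 for circadian clock genes and 0.81 for immediate-early and stress genes. Lists with a lower response had medians of -0.36 for endothelial markers, -0.33 for smooth muscle and pericyte markers, -0.49 for erythrocyte genes and -0.48 for fatty acid oxidation. All of these list calls were lost with an estimated correlation. Acta1 was limited by its Balb/C sham signal, near the top of the scale.

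A test of the difference of AngII responses between the strains in Bmx-deficient mice passed for 138 genes. Strain could not be told apart from file or the names KO and TK. Responses higher in deficient Balb/C mice were those of Ciart at 4.92, Per2 at 4.66, Dbp at 3.60, Per3 at 2.54, Per1 at 2.51, H2ac22 at 2.30, H2ac7 at 2.08, H2ac24 at 1.99, Csrnp1 at 1.98 and Nr1d2 at 1.93. Lower ones were those of Pdk4 at -3.10, Spon2 at -2.74, Angptl4 at -2.38, Arntl at -2.37, Mmp3 at -1.95, Vgll3 at -1.95, Acta1 at -1.87, Fads6 at -1.70 and Hpgd at -1.67. The response was lower, with no size as groups lay at background, for Cib3 (adjusted p = 0.0114). Lists with a higher response had medians of 0.35 for IL-6 family and STAT3 genes, 0.51 for atrial myocyte genes, 0.65 for cell cycle, 1.65 for circadian clock genes and 0.48 for immediate-early and stress genes. All of these list calls were lost with an estimated correlation. Acta1 stood as near the top of the scale as in wild type.

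In other splits of the same 6 arrays into 3 and 3, the real AngII comparisons gave 855 and 402 genes in C57Bl/6J wild type and deficient mice and 3972 and 1431 in Balb/C, against a highest other of 0 in each, and 1 of 10 splits, the real one, reached the real value. For the genotypes under AngII the real values were 18 in C57Bl/6J and 1146 in Balb/C, the highest others 1 and 2, and 1 of 10 splits reached the real value. For the genotypes in sham all 10 of 10 splits gave 0. With 10 splits they are too few for a share under 0.05.

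For differences of responses 100 splits were counted. The real value was reached by 9 splits in C57Bl/6J (6 genes, highest other 10), 8 in Balb/C (225, highest other 846), 13 between strains in wild type (1543, highest other 3996) and 12 between strains in deficient mice (138, highest other 2161), the real split included. All of the other splits that reached it, 8, 7, 12 and 11, kept a pair of groups whole, and among splits without a whole pair the highest counts were 1, 0, 1 and 0. Splits with a whole pair keep that pair's real difference, so these counts cannot decide on chance.

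In C57Bl/6J wild type mice after AngII, 17 of the 18 genes called between genotypes under AngII had 3 arrays apart from the other 9, Cited2 being the exception, and Mmrn1 was detected on 3 of 3 of these arrays and 0 of the other 9. An AngII response that needs Bmx in both strains is argued against for the genes as a set. Their sign-aligned median response in Balb/C wild type was 0.16 (interval -0.0858 to 0.408) against 1.17 in C57Bl/6J. It stays open for Tmem254a and Lgr6, which responded in Balb/C by 1.03 and -1.02 with genotype differences under AngII of -0.79 and 0.67. The same holds for Serpina3n, which responded by 2.34 with a difference of -0.45 that did not pass (adjusted p = 0.323). It is undecided for Tnfaip8, Pim3 and Tmem181a. Their genotype differences of 1.12, 0.86 and -0.66 followed C57Bl/6J, but their Balb/C wild type responses of -0.21, -0.58 and 0.04 did not pass. An inherited difference between these mice and the others may remain, since 3 called genes, Plac9a, Gm9780 and Tmem254a on chromosome 14 of GRCm38.p6, lay within 1 Mb of another called gene, and some C57Bl/6 lines are known to lack Mmrn1. A batch or hybridization difference of the 3 arrays cannot be told apart from it, as a share of 0.034 of 10000 random gene sets had as many neighbouring genes (median 0, highest 8). The origin of the wild type AngII mice was not given.

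Matrix genes of Balb/C responded less to AngII in Bmx-deficient mice, with a median difference of -1.23 (adjusted p = 0.18 with an estimated correlation). A weaker response of all genes alike is argued against by random lists matched for response, which had a median of -0.74 and a central 95% of -0.937 to -0.519, and a share of 1e-04 as low, the least possible, and, since such lists leave out the correlation between genes, by the mean of matrix minus matched genes on each array, which differed by -0.432 (interval -0.772 to -0.0906). Normalization or background correction is argued against by 4 alternatives, relative to all genes, of -0.924 to -1.28. Fewer fibroblasts with unchanged expression per cell stays open. Under AngII 19 fibroblast markers outside the list were lower too, at -0.547 (interval -0.823 to -0.265) against -1.30 for 50 matrix genes. They stood 0.972 above these over arrays (interval 0.7 to 1.24), but were not shown to follow fibroblast number alone. A part of Bmx in this response and a difference in pressure or dose of AngII, which were not given per animal, stay open and untested. The 8 in 100 splits for the difference of responses cannot decide on chance here either.

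Probes of the same gene moved apart between AngII and sham: in 1875 genes with a pair of bright probes, the first component of the difference between the probes held 57.4% of variance in Balb/C and 31.3% in C57Bl/6J and separated AngII from sham. Background correction or normalization used here is argued against, because the shifts correlated at 0.963 or more with those without background correction, under median scaling and from the authors' values. A change in transcript forms with AngII stays possible, with shifts that correlated between the strains at 0.531 (highest of shuffled genes 0.0954). RNA quality or labelling that varies from sample to sample stays possible too, because 1.45% of the variance between sham replicates of Balb/C lay along the axis of the other strain (highest of shuffled axes 0.327) and 3.30% in C57Bl/6J (highest 0.25). Among the examples, the probes of Nmrk2 moved by 3.37 and -2.02 in Balb/C wild type, those of Mff by -0.72 and 1.31 and those of Rb1 by 1.03 and -0.66.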

How the results depend on the processing

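The slide could not be used as a block because no slide information was given, and the replicate numbers did not pair samples: after group means were removed, arrays with the same number correlated at a median of -0.0277 in C57Bl/6J and -0.00394 in Balb/C. Chosen after the values were seen were the mean of detected probes, the list medians under other normalizations, and leaving out arrays between strains. Of the counts, correlations and list-test counts 167 values stayed within a margin and 89 moved, with causes not tested unless stated. For AngII in C57Bl/6J wild type, 1215 against 855 counted as within it and 1303 as moved. Of list medians 201 stayed within a margin, 229 moved and 5 reversed, all 5 under median scaling in Balb/C. Such scaling by construction lets the median of all genes move. Endothelial genes in sham turned from -0.20 to 0.0471 and smooth muscle genes under AngII from 0.19 to -0.10. In the difference of responses adult myocyte genes turned from 0.12 to -0.0804, smooth muscle genes from 0.13 to -0.27 and oxidative phosphorylation from 0.19 to -0.10. Of list tests 376 stayed, 130 were weaker and 14 stronger, and of named-gene tests 13421 stayed, 1056 were weaker and 39 stronger. Under median scaling the count was 487 for AngII in C57Bl/6J wild type (main value 855), 664 for AngII in deficient Balb/C mice (1431), 2153 for the Balb/C genotypes under AngII (1146), 766 for the Balb/C difference of responses (225), 2442 between strains in wild type (1543) and 20 in deficient mice (138). No background correction gave 713 for AngII in deficient C57Bl/6J mice (402), 31 for the C57Bl/6J genotypes under AngII (18) and 14 for the C57Bl/6J difference of responses (6), and the larger offset gave 678, 32 and 14 for the same. The authors' values gave 709, 29 and 17, and the trended prior 754, 38 and 12. Correlation of the C57Bl/6J responses was 0.6435 without background correction and 0.6433 with the authors' values (main value 0.57), and that of the wild type responses across strains 0.5275 and 0.5272 (0.51). Without a filter the Balb/C difference of responses gave 110 and the difference between strains in deficient mice 78, and a stricter filter gave 11 for the C57Bl/6J difference of responses. All detected probes, counted as probes and so larger by construction, gave 1303 for AngII in C57Bl/6J wild type, 689 in deficient mice, 1 for the C57Bl/6J genotypes in sham (0), 6791 for AngII in Balb/C wild type (3972) and 2652 in deficient mice. The mean of detected probes gave 12 for the C57Bl/6J difference of responses. Array weights gave 13 there, 2416 for AngII in deficient Balb/C mice, 2040 for the Balb/C genotypes under AngII, 720 for the Balb/C difference of responses and 648 between strains in deficient mice. Replicate number as a block gave 253 for AngII in deficient C57Bl/6J mice and 11 for the genotypes under AngII, and only the groups compared gave 207 and 7. Leaving out 1 array gave, from lowest to highest, 455 to 695 for AngII in C57Bl/6J wild type, 45 to 196 in deficient mice, 9 to 24 for the genotypes under AngII and 4 to 8 for the difference of responses, and in Balb/C 3129 to 3594, 700 to 1167, 473 to 1651 and 74 to 470, with 0 for the genotypes in sham in both strains. Between strains it gave 1099 to 1453 in wild type and 42 to 227 in deficient mice. With the estimated correlation camera passed for 2 lists in the AngII response of C57Bl/6J wild type and for 0 in every other comparison within a strain. Fry passed for 0 lists in the C57Bl/6J genotype comparisons in sham and under AngII, 0 in the C57Bl/6J difference of responses, 0 in the Balb/C genotypes in sham, 15 for AngII in Balb/C wild type and 3 in the Balb/C difference of responses. Of the named genes that passed, those that kept their call under every alternative that tested them were 47 of 67, 25 of 41, 6 of 16 and 4 of 5 in C57Bl/6J, for AngII in wild type and in deficient mice, the genotypes under AngII and the difference of responses, and 88 of 104, 49 of 82, 61 of 92 and 15 of 46 in Balb/C, with 16 of 20 and 12 of 20 between strains in wild type and deficient mice. Tested without each array and kept were 41, 10, 7 and 3 in C57Bl/6J and 99, 53, 58 and 20 in Balb/C. A dim signal limits folds: where 1 of 2 groups lay at background only a smallest fold was given, and differences of responses that use such a group were given no size.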

Other observations

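In Balb/C, Nppb, a peptide released by stretched myocytes, read 14.65 on all 3 arrays of wild type AngII mice and between 13.64 and 14.65 in deficient AngII mice. On the wild type AngII arrays it was the second brightest probe, with signals of 25273.8 to 29778 before normalization, and quantile normalization gave it the same value on each. Its AngII response in wild type was 0.98, and 1.27 under median scaling.

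In Balb/C wild type mice Agtr1a, a receptor for angiotensin II, fell at -1.24 ± 0.22 after AngII and was higher by 1.12 ± 0.22 in the deficient mice under AngII, while the converting enzyme gene Ace rose by 1.32 ± 0.15 in wild type and was lower at -1.19 ± 0.15 in the deficient mice. The difference of responses passed for Ace at -1.05 ± 0.22 (adjusted p = 0.0193) with limma. In C57Bl/6J wild type the receptor gene Mas1 fell at least 1.08-fold, to a signal detected on none of the 3 AngII arrays.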
